A study of Halobacterium salinarum NRC-1 with 48 samples.

How the data were processed

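Two-colour oligonucleotide arrays of Halobacterium salinarum NRC-1 were analysed from 48 scanner files and from the authors' value table of the series. Per the file headers, the deposited scanner files give the mean, peak and local background intensity of each spot for the dyes Alexa 547 and Alexa 647 on a linear scale. The former dye is named as in the labels. The scanner headers give it a neighbouring number, and it was read as the same channel. The deposited value table holds log10 ratios by comparison with the scanner values. Each of its columns correlated with the log10 ratio of the Alexa 547 to the Alexa 647 mean spot intensity of that array, with r between 0.656 and 0.989 across spots, so its direction and scale were read from the values. The authors' background correction, normalization and centring are not given in the sources used here. The column medians of that table lay between -0.07 and 0.25 on the log10 scale and are listed per array in the results. Spot order in the scanner files was matched to the identifiers of the table through the grid position of each spot.

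Samples were placed in the entrained or mock arm from the descriptions and growth protocols in the labels, since titles do not separate the arms. Each of 24 conditions, 12 time points in each of 2 arms, had 2 arrays as a dye exchange. The ratio of every array was turned to sample over reference from the labelled dyes. The turned ratios of the arrays of each exchange correlated positively in 24 of 24 conditions, with a median r of 0.518 and a range from 0.141 to 0.75. Arrays of 1 dye orientation correlated at 0.489 or above with Alexa 547 and at 0.675 or above with Alexa 647 on the sample. No arrays held identical intensities.

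Each array has 10752 spots in sets of 4 for 2688 probes. Intensities were corrected with normexp at an offset of 50 and normalized by loess within each array in limma 3.58.1 under R 4.3.3. Spots that lacked a value in the authors' table on 1 or more arrays had no weight in the loess and were left out, which removed 288 probes and left 2400. This set was chosen after the values were inspected and before any test. The spots of a probe were averaged, then the 2 arrays of an RNA. Saturated spots were kept. Of the named genes, csg was saturated on every array of both arms and is not reported, and none lay at or below local background on every array of an arm. Between 1.11% and 58.1% of spots per array were at or below local background in the Alexa 547 channel. The range was 0.502% to 36.3% in the Alexa 647 channel, and such spots limit dim probes. In the Alexa 547 channel it was 1.11% to 38.2% on entrained arrays and 9.91% to 58.1% on mock arrays. Background therefore differed between the arms compared. It also differed within the entrained arm, between the array groups described in the results. Gene symbols came from a platform annotation that pairs 133 of the tested probes with 1 symbol each, none with several, and 2267 with none. That annotation can be old, and the names were kept as given. A genome of this strain was not used here.

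Designs, gene lists, named genes and most alternatives were fixed before the data were examined. The arm difference was tested with lmFit and eBayes with the time point as a block. Rhythms were tested with a moderated F on cosine and sine terms of 24 h beside a linear trend per arm, and trends with a linear slope per arm, given per 24 h. Benjamini-Hochberg adjusted p under 0.05 was the threshold throughout, for 7 sets of tests over all probes. Gene lists were tested with camera at a preset correlation of 0.01, and their rhythms by 100000 permutations of residuals of the list score, adjusted over 10 lists. Lists with fewer than 3 measured members were not tested. The fixed expressions also took carA and carB into chemotaxis and panB into chaperones and proteasome. Membership of translation factors and tRNA synthetases was read from symbols, because products were not used here. The genes to name were those past the threshold, ranked by size, with the same sign at 11 or 12 of 12 times for the arm difference. Where fewer than 5 named genes passed, all of them and the 10 with the smallest p were given. To these were added bat, hop, sop1, sop2 and arcA in every case. The plan also named bop and phr, cir, gvp, dms and cox genes, which could not be looked up for lack of symbols. Of each list the 4 members with the smallest p are given for the arm difference.

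The fits were tested on simulated data with the spread of the real arrays, in which 200 of 2400 probes carried known changes. The simulated noise was independent between probes and times, without run, dye or drift effects, so recovery in the real data can be lower. An arm difference of 0.5 was recovered for 97% of them. Changes below 0.5 were not simulated, and the arm differences of the named genes called below were smaller than that. Alternatives were no background correction, median centring, Aquantile scaling, the authors' value table, leaving out the 25% of probes with the lowest intensity, each dye orientation alone, all 48 arrays with the RNA as a random block, leaving out each time point, other terms for time, and periods of 12 and 18 h. Chosen after seeing the data were the array run as a block, the array run that holds both arms alone, all 2688 probes, a dye term, leaving out 1500 and 1620 min, the run block with an estimated correlation, gene lists without background correction, and lists without carA, carB and panB. An overview of the counts and of some alternatives was seen before the simulations were run and before these additions were made.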

Results

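Transcript levels of Halobacterium salinarum NRC-1, an archaeon of hypersaline waters, were measured over a day in cultures with and without a history of light and dark cycles. In the entrained arm, cultures grown with air at 37 °C had received 12 h of light at 159 µE per square metre per second and 12 h of dark per cycle for 72 h. In the mock arm they had been kept in the dark for 72 h. RNA was taken from both arms at the same 12 times between 1380 and 2880 min after the end of this treatment, that is from 23 to 48 h. Each of the 24 RNA samples was hybridised on 2 arrays with the dyes exchanged, against a common reference RNA from mid-logarithmic growth. The median spot intensity per array lay between 657 and 2444 in the Alexa 547 channel and between 333 and 2598 in the Alexa 647 channel. All values below are log2 ratios of sample to reference, averaged over the 2 arrays of an RNA, and the number of arrays limits their precision. No condition had a second RNA, so the time points stood in for replicates and p-values measured consistency over time. Nothing in the labels says that the samples came from separate cultures. Of 2400 probes tested, 133 carried a gene symbol and the other 2267 are counted without a name.

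The first comparison asked which transcripts differed between the entrained and the mock arm over the whole window. Transcripts of the cobalamin synthesis gene cbiG were lower in entrained cultures, at a mean of -0.39 against -0.07, a difference of -0.33 ± 0.05 (SE) with the lower value in the entrained arm at 12 of 12 times (limma, adjusted p = 0.00625). Transcripts of glyA, which encodes serine hydroxymethyltransferase, were higher in entrained cultures by 0.24 ± 0.05 (SE) at 12 of 12 times (limma, adjusted p = 0.0365). Those of sucD, a subunit of succinyl-CoA synthetase in the tricarboxylic acid cycle, were higher by 0.18 ± 0.04 (SE) at 11 of 12 times (limma, adjusted p = 0.0416). In all, 42 of 2400 probes passed, 31 higher and 11 lower in entrained cultures, and 472 had an unadjusted p under 0.05, where chance gives 120. The calls for glyA and sucD ended with median centring in place of loess, where the differences were 0.12 and 0.04, and with the authors' value table, where they were 0.14 and 0.10. The split of higher and lower calls turned with the scaling, to 25 higher and 37 lower with median centring and to 3 higher and 7 lower in the authors' value table. Of the 42 probes, 25 passed with median centring and 5 in the authors' value table. The call for glyA also ended without any 1 of 8 of the 12 times (1440, 1800, 1980, 2160, 2220, 2340, 2520 or 2700 min) and that for sucD without any 1 of 10 (each time but 1380 and 1800 min), with differences of 0.21 to 0.26 and 0.17 to 0.20, while cbiG passed without each. The calls for all 3 genes ended with the sample in Alexa 547 alone, where cbiG differed by -0.41 and 4 probes passed, and those for glyA and sucD also with the sample in Alexa 647 alone, where 20 passed. Leaving out 1 time point gave 9 probes without 2220 min, 9 without 2520 min, 16 without 2340 min, 24 without 2880 min, 25 without 1980 min and 65 without 1380 min.

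The 10 named genes next in order did not pass. Two-component and motility genes were among them. Entrained minus mock differences were 0.21 for the response regulator cheY, 0.18 for the methylesterase cheB and 0.20 for the transducer htr7. Over the alternatives they ran from 0.08 to 0.26 for cheY, 0.06 to 0.21 for cheB and 0.10 to 0.32 for htr7. The others were cbiT at -0.28, hisG at 0.22, sucC at 0.14, mvk at 0.24, thiC at 0.14, gatA at 0.14 and endA at -0.24, and the adjusted p of these 10 genes ran from 0.0525 for cheY to 0.117 for endA. The value for thiC turned to -0.03 with median centring and -0.05 in the authors' value table. Over the alternatives that for endA ran from -0.62 to -0.07 and that for sucC from 0.05 to 0.21. None of the 6 light-related genes with a symbol among the tested probes passed. Others named in the plan, such as bop and the phr and cir genes, could not be looked up, and unnamed probes may include them. The difference was 0.03 ± 0.06 (SE) for bat, a regulator of bacteriorhodopsin synthesis, 0.06 ± 0.05 for hop, the halorhodopsin gene, and 0.01 ± 0.04 for sop1, a sensory rhodopsin gene. It was -0.13 ± 0.05 for sop2, the other sensory rhodopsin gene (limma, adjusted p = 0.193). For arcA, which encodes the arginine deiminase of arginine fermentation, it was 0.01 ± 0.04, and -0.07 with median centring.

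**Figure D1:**
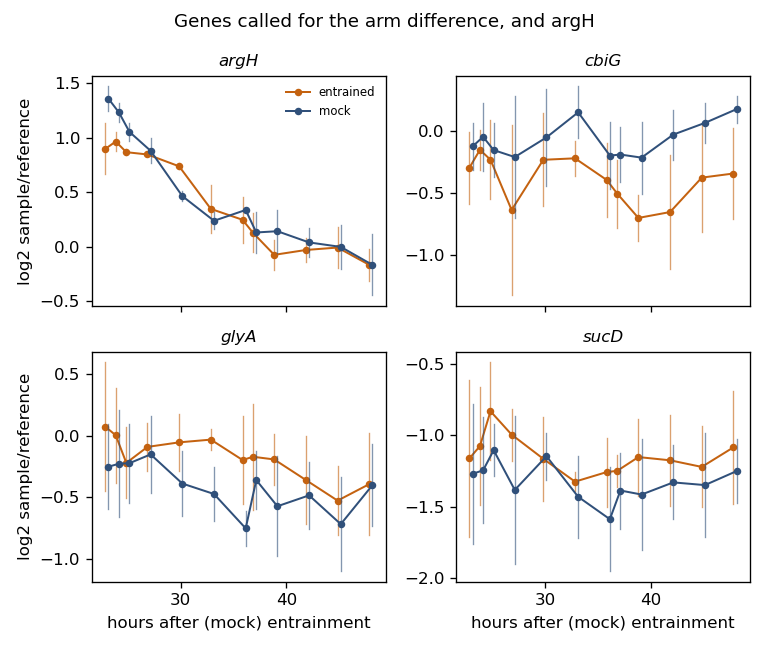
Log2 ratio of sample to reference (vertical axes) against hours after entrainment or mock entrainment (horizontal axes) for argH, cbiG, glyA and sucD. Points are the mean of 2 dye-exchanged arrays of 1 RNA, vertical lines join those 2 arrays, and the arms are shifted sideways by a fixed small step. The entrained cbiG points lie below the mock points at 12 of 12 times, and argH falls in both arms.

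Of 10 gene lists fixed beforehand, cobalamin synthesis stood lower in entrained cultures. Its 4 measured members had a mean difference of -0.17, with 3 members lower and 1 higher and the list mean lower at 11 of 12 times (camera, adjusted p = 0.0241). The call ended with an estimated correlation (camera, adjusted p = 0.155) and without background correction, where the mean was -0.10 (camera, adjusted p = 0.15). At the preset correlation it stayed with median centring at a mean of -0.24 (camera, adjusted p = 0.00147) and in the authors' value table at -0.17 (camera, adjusted p = 0.000371). An estimated correlation was not tried with these scalings. After cbiG and cbiT its members were cbiQ at -0.08 and cobN at 0.02, of which cbiG passed over all genes tested and 2 passed when adjusted over the list alone. In DNA replication the differences were -0.13 for gyrA, -0.19 for gyrB, -0.09 for orc8 and -0.04 for orc7, with 1 of the 4 higher without background correction, and the list did not pass (camera, adjusted p = 0.118), although 2 members passed when adjusted over the list alone. In the tricarboxylic acid cycle 4 members were higher and 2 lower (camera, adjusted p = 0.653), with sucD past the threshold over all genes and 2 members past it when adjusted over the list alone, but 2 members were higher and 4 lower with median centring and in the authors' value table. Among 13 chemotaxis members, which by the fixed rule included the carbamoyl phosphate synthase genes carA and carB, 7 were higher and 6 lower (camera, adjusted p = 0.832), with 5 higher and 8 lower without background correction. Of these members 4 passed when adjusted over the list alone, namely cheY, cheB, htr7 and carA. Phototrophy had 4 members higher and 2 lower (camera, adjusted p = 0.832), and 2 higher and 4 lower without background correction. Chaperones and proteasome had 4 higher and 2 lower, or 3 and 3 with median centring (camera, adjusted p = 0.538), purine and pyrimidine synthesis 6 higher and 4 lower (adjusted p = 0.832), and translation factors and tRNA synthetases 7 higher and 6 lower (adjusted p = 0.947). DNA repair had 2 higher and 2 lower, with 1 member past the threshold when adjusted over the list alone (camera, adjusted p = 0.832). Iron and haem had 2 higher and 1 lower (camera, adjusted p = 0.832), or 1 higher and 2 lower with median centring. Members with the smallest p in these lists, none of them past the threshold over all genes, were mutL (0.21), uvrA (-0.14), radB (0.07) and uvrB (-0.03) in DNA repair, and panB (0.26), psmB (0.12), psmA (0.08) and dnaJ (-0.06) in chaperones and proteasome, where panB entered by its symbol and belongs to pantothenate synthesis. They were ileS (0.12), aspS (-0.10), infB (-0.15) and hisS (0.08) in translation, guaB (-0.09), purE (-0.07), pyrI (0.06) and purL (0.06) in purine and pyrimidine synthesis, and hemA (0.05), dpsA (0.04) and hemL (-0.01) in iron and haem. After the genes already given came htr2 (-0.06) in phototrophy, citZ (-0.11) and mdh (-0.07) in the tricarboxylic acid cycle and carA (-0.13) in chemotaxis. Mean and median differed in sign for phototrophy (-0.01 and 0.01), translation (-0.0045 and 0.03) and purine and pyrimidine synthesis (-0.0029 and 0.0091).

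The arrays fell into 3 groups, called runs here, by the number of spots left blank in the authors' table (677, 1010 or 1097). That these were separate runs was inferred and is not given by the labels. The arms were spread unevenly over them. A first run held 18 entrained arrays up to 2340 min, a second held 6 entrained arrays and 22 mock arrays, and the last held the 2 mock arrays of 2880 min. With the array run as a block, which leaves the arm difference to the 2 times at which both arms lay in the same run, 0 of 2400 probes passed in limma and 159 had an unadjusted p under 0.05. Within the second run alone 0 passed and 350 had an unadjusted p under 0.05. There the times were unmatched, with entrained RNAs from 2520 to 2880 min and mock RNAs from 1380 to 2700 min. That fit therefore rested on a linear time term. The difference for cbiG was -0.53 with the block and -0.43 within the second run beside the time term. For glyA it was 0.16 and 0.25, and for sucD 0.14 and 0.27, none past the threshold. The cobalamin synthesis list had a mean difference of -0.20 with the block, against -0.17 without it, and did not pass (camera, adjusted p = 0.253).

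The second comparison asked whether a rhythm of 24 h, such as the light and dark cycle could leave behind, differed between the arms. The window of 25 h held about 1 cycle, so a repeating rhythm could not be told from another curved change. No named gene and no unnamed probe passed. The interaction of arm and rhythm gave 0 of 2400 probes in limma, with 101 at an unadjusted p under 0.05 where chance gives 120. With the sample in Alexa 647 alone 1 passed and 260 had an unadjusted p under 0.05, against 50 in the authors' value table and 60 with median centring. The genes with the smallest p were argH (amplitude of the difference 0.27), the histidine degradation gene hutG (0.46), nadC (0.36), phnE (0.25), eno (0.14), truA (0.34), cheB (0.15), htr1 (0.15), glyA (0.16) and glyS (0.23), each with an adjusted p of 0.990 or above. The amplitude of the difference was 0.04 for bat, 0.12 for hop, 0.06 for sop1, 0.14 for sop2 and 0.16 for arcA. In simulated data with the spread of these arrays, 70% of 200 probes given an amplitude of 0.5 in 1 arm were recovered in this comparison. The simulated noise was independent between probes and times, so recovery in the real data can be lower. Amplitudes below 0.5 were not simulated.

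Within the entrained arm 0 of 2400 probes passed for a 24 h rhythm in limma, and 361 had an unadjusted p under 0.05. That number was 187 without 1980 min, 587 without 2880 min and 203 in the authors' value table, and a period of 18 h in place of 24 h gave 593. From the arrays with the sample in Alexa 647 alone 17 passed, and 1 passed without 2340 min and 1 without 2520 min. The 10 named genes with the smallest p did not pass. They were hutG (amplitude 0.40, highest at 7.11 h of the 24 h cycle counted from the end of entrainment), sop2 (0.27, highest at 18.2 h), htr1 (0.18, highest at 9.45 h), pyrI (0.16), argH (0.16), cbiT (0.24), ndk (0.22), eno (0.16), purL (0.19) and rpl12p (0.20), with adjusted p from 0.256 to 0.279. Within the mock arm 0 of 2400 passed in limma and 111 had an unadjusted p under 0.05, or 212 with the sample in Alexa 647 alone, 72 without 2880 min and 104 at a period of 18 h. The 10 genes there, none of which passed, were argH (0.22), pyrI (0.13), leuS (0.17), sop2 (0.20), arcA (0.15), pyrB (0.19), gdhA2 (0.26), hisI (0.19), phnE (0.16) and gdhA1 (0.14), with adjusted p from 0.215 for argH to 0.971. For bat the amplitude was 0.09 in each arm, for hop 0.13 in the entrained and 0.01 in the mock arm, for sop1 0.03 and 0.07, and for arcA 0.04 in the entrained arm. In simulated data with independent noise an amplitude of 0.5 in the entrained arm was recovered for 90.5% of 200 probes.

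**Figure D2:**
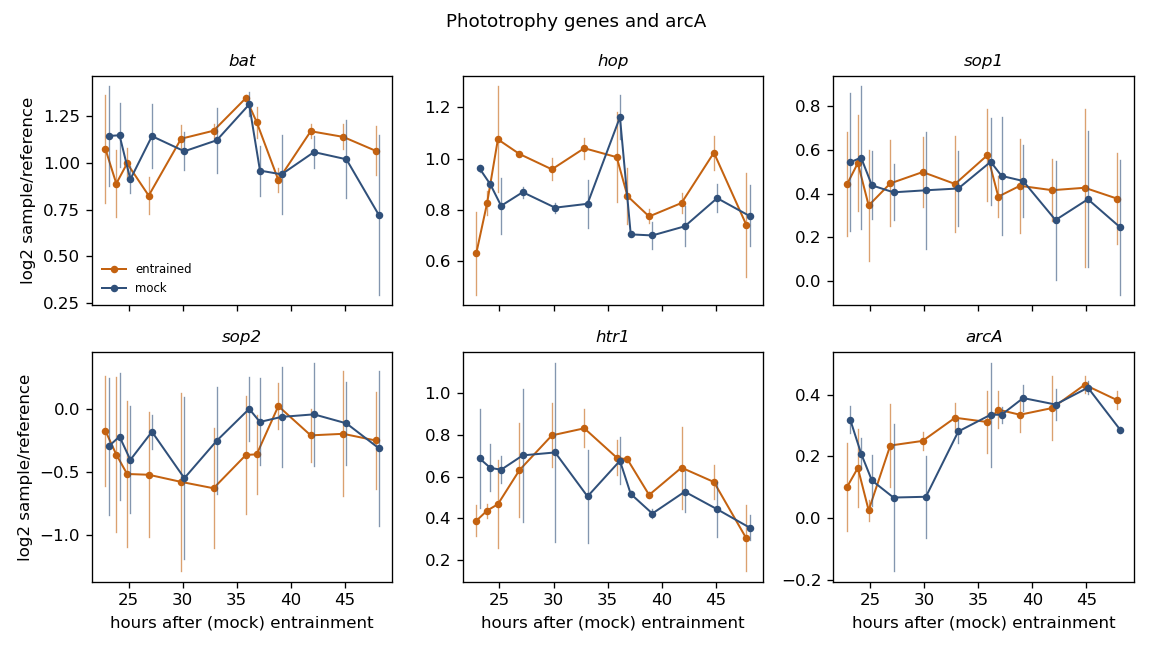
Log2 ratio of sample to reference (vertical axes) against hours after entrainment or mock entrainment (horizontal axes) for the light-related genes bat, hop, sop1, sop2 and htr1 and for arcA. Points are the mean of 2 dye-exchanged arrays of 1 RNA and vertical lines join those 2 arrays. Entrained points lie above mock points at 8 of 12 times for bat, at 8 of 12 for hop and at 3 of 12 for sop2.

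Of the 10 gene lists none passed for a difference in rhythm between the arms. The smallest unadjusted values were those of cobalamin synthesis (amplitude of the scaled list score 0.40, permutation test, p = 0.0306, adjusted p = 0.226) and chemotaxis (0.29, permutation test, p = 0.0451, adjusted p = 0.226). In the entrained arm alone the cobalamin synthesis score had a 24 h amplitude of 0.59 with its highest value at 23.5 h (permutation test, p = 0.00029, adjusted p = 0.0029), and in the mock arm an amplitude of 0.20 (permutation test, p = 0.313). The entrained call ended with median centring (adjusted p = 0.453), with the authors' value table (adjusted p = 0.101) and without background correction (adjusted p = 0.0531). Next in the entrained arm were chemotaxis (adjusted p = 0.0825) and translation factors and tRNA synthetases (adjusted p = 0.0894), neither past the threshold. These p-values are approximate, because successive time points are not exchangeable where values drift. The cobalamin synthesis peak lay near both ends of the window of 25 h, so it cannot be told from a bend or step over time. List rhythms were not tested with the array run as a block.

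The third comparison asked which transcripts changed steadily over the window in each arm. The steepest change among named genes was the fall of argH, the argininosuccinate lyase gene of arginine synthesis, in both arms. Its slope per 24 h was -1.19 ± 0.13 (SE) in entrained cultures (limma, adjusted p = 5.96e-06) and -1.40 ± 0.13 in mock cultures (limma, adjusted p = 2.53e-07), from ratios of 0.90 and 1.36 at 1380 min to -0.17 in both arms at 2880 min. In entrained cultures gdhB also rose, with a slope of 0.40 ± 0.10 (limma, adjusted p = 0.0387), a call that ended without any 1 of 8 of the 12 times (1380, 1440, 1500, 2220, 2340, 2520, 2700 or 2880 min). Over the 12 omissions its slope was 0.30 to 0.44. The call ended in 13 of 25 alternatives in all, among them each dye orientation alone (0.27 and 0.53), 24 h terms (0.45), the array run as a block (0.55) and all probes on the array (0.40). The largest slope was 0.72, in the authors' value table, where the call stayed. In mock cultures infB, a translation initiation factor, rose by 0.68 ± 0.16, the cysteinyl-tRNA synthetase gene cysS by 0.53 ± 0.13 and the pseudouridine synthase gene truA by 0.93 ± 0.24 (limma, adjusted p = 0.0211, 0.0267 and 0.028). The mock slopes of these 3 genes differed between the dye orientations, at 0.07 and 1.28 for infB, 0.20 and 0.87 for cysS and 0.08 and 1.78 for truA in the single orientations, and all 3 calls ended in the authors' value table and without background correction. Single times also ended them, namely 1380, 2520 or 2700 min for infB, 1440, 1500, 2520 or 2700 min for cysS, and 1380, 1440, 2340, 2520 or 2880 min for truA. Over the 12 omissions the slopes nonetheless stayed at 0.57 to 0.76 for infB, 0.45 to 0.62 for cysS and 0.80 to 1.03 for truA.

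In the entrained arm 31 of 2400 probes passed, 16 rising and 15 falling, and in the mock arm 79 passed, 37 rising and 42 falling, with 25 past the threshold in both arms. The split became 13 rising and 9 falling in the entrained arm and 37 rising and 15 falling in the mock arm with median centring, and 19 and 6 and 22 and 9 in the authors' value table. With the array run as a block 15 entrained and 40 mock probes passed. Array number rose with time in both arms, so time and array order ran together. The entrained count was 15 without 1440 min, 16 without 2880 min, 18 without 2520 min, 20 without 1500 min and 48 without 1380 min. The mock count was 25 without 1440 min, 28 without 1380 min, 32 without 2520 min, 35 without 2880 min, 51 without 2700 min and 52 without 2220 min.

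Other named genes did not pass in the arm concerned. In entrained cultures the slopes were -0.42 for glyA, 0.33 for rimI, 0.31 for arcA, -0.35 for moaC and 0.28 for hemA. They were -0.48 for endA, 0.33 for arcC, -0.40 for serB, 0.32 for fer2 and -0.35 for nadA. The adjusted p of these 10 genes ran from 0.0575 to 0.234 (limma). Among the wider ranges over the alternatives were -0.94 to -0.03 for endA, 0.09 to 0.56 for rimI, 0.11 to 0.50 for arcA and 0.13 to 0.43 for hemA. In mock cultures the slopes were 0.38 for eno, -0.47 for carB, -0.43 for purM, -0.37 for glyA and -0.34 for htr6. They were 0.28 for rimI, 0.26 for thiC, -0.36 for cobN, 0.50 for phoU and -0.27 for map. The adjusted p of these 10 genes ran from 0.051 to 0.0941 (limma). The slope of purM was 0.01 without background correction and that of phoU was -0.18 and 1.18 in the single dye orientations. Entrained and mock slopes were 0.17 and -0.20 for bat, -0.03 (0.07 in the authors' value table) and -0.12 for hop, -0.05 and -0.19 for sop1 and 0.25 and 0.20 for sop2, and the mock slope of arcA was 0.22.

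Slopes did not differ detectably between the arms. The interaction of arm and time gave 0 of 2400 probes in limma, with 118 at an unadjusted p under 0.05. That number was 67 without 1440 min, 74 without 2880 min, 178 without 1620 min, 286 with the sample in Alexa 547 alone and 40 in the authors' value table. The 10 named genes with the smallest p had entrained minus mock slopes of -0.59 for cysS, -0.69 for endA, 0.38 for hemA, -0.99 for truA, -0.62 for hisD, 0.37 for bat, -0.39 for cbiG, 0.48 for moaA, -0.55 for folP and 0.32 for purM, each with an adjusted p of 0.911. The slope difference was 0.09 for hop, 0.14 for sop1, 0.05 for sop2 (-0.10 without background correction, -0.07 with median centring and -0.14 in the authors' value table) and 0.09 for arcA (-0.02 with median centring). Those of moaA and purM were -0.06 and -0.12 without background correction, that of truA was 0.01 in the authors' value table, and those of endA, truA and hisD were 0.16, 0.29 and 0.04 in a single dye orientation. Without 1500 and 1620 min 2 probes passed, truA at -1.41 among them. In simulated data with independent noise a slope difference of 0.5 was recovered for 19% of 200 probes and one of 1 for 88%. No gene list passed for a slope in either arm or for the slope difference. Without background correction cobalamin synthesis passed in the entrained arm at a mean slope of -0.29 (camera, adjusted p = 0.0236). An estimated correlation was not tried there, and with background correction it gave an adjusted p of 0.508 for this list (camera). With that correction the smallest adjusted p was 0.138 for the slope difference of phototrophy, with 5 members higher and 1 lower (4 and 2 with median centring), and of iron and haem, with 2 higher and 1 lower, where 1 member passed when adjusted over the list alone. For cobalamin synthesis the adjusted p was 0.24 in the entrained arm, where the slopes were -0.29 for cobN, -0.42 for cbiT, -0.22 for cbiG and -0.02 for cbiQ (3 of 4 below 0 in the authors' value table) and 2 passed when adjusted over the list alone. In the mock arm infB and cysS were the 2 members of translation factors and tRNA synthetases past the threshold over all genes, and 2 members of that list, 2 of chemotaxis, 1 of purine and pyrimidine synthesis and 1 of cobalamin synthesis passed when adjusted over the list alone. Those 2 of chemotaxis were htr6 and carB, which entered by its symbol. With the array run as a block the slope of cobalamin synthesis passed in the entrained arm, with a mean of -0.54 against -0.24 without the block (camera, adjusted p = 0.00306, or 0.0176 with an estimated correlation). It also passed there for the slope difference, with a mean of -0.46 against -0.21 (camera, adjusted p = 0.00822, or 0.032 with an estimated correlation). In the entrained arm the runs followed one another in time, so the block takes up part of the change with time. These larger slopes therefore rest on the trend within each run.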

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

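Chosen after seeing the data were the array run as a block or taken alone, all probes on the array, the dye term, leaving out 1500 and 1620 min together, the run block with an estimated correlation, lists without background correction, and lists without carA, carB and panB. For differences and slopes of single named genes, Aquantile scaling apart, 1422 values under an alternative kept direction and side of the threshold, 85 no longer passed, 97 newly passed and 39 turned sign. Of their 24 h amplitudes, which cannot turn sign, 1126 kept their side and 4 newly passed. The fall of argH passed in both arms under all 25 alternatives, from -1.46 to -0.81 in the entrained and from -1.60 to -0.95 in the mock arm. The arm difference of cbiG passed in 24 of 27 (-0.53 to -0.24), that of glyA in 11 (0.12 to 0.28) and that of sucD in 7 (0.04 to 0.27). Aquantile scaling leaves ratios as they are and so says nothing about stability. Except where an alternative uses fewer probes or samples, the cause of a change was not tested. Spots near local background, up to 58.1% of an array, limit dim probes.

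The 42 probes differing between the arms became 136 without background correction, 10 in the authors' value table, 148 with all 48 arrays and 157 with a dye term besides, 26 without the time block, 70 with smooth terms for time, 27 with all probes, and 0 with the array run as a block or within the shared run (limma, 159 and 350 at an unadjusted p under 0.05). These were in part other probes. Of the 42, 31 passed without background correction, 5 in the authors' value table, 32 with all 48 arrays and 42 with the dye term. The count ranged from 4 to 65 with 1 dye orientation or 1 time left out. The 31 entrained trends became 48 without the dimmest 25% of probes, 73 with all arrays, 67 with the dye term, 19 with 24 h terms, 15 with the run block and 20 with all probes, and ranged from 14 to 48 with 1 part left out. The 79 mock trends became 52 with median centring, 31 in the authors' value table, 125 with all arrays, 121 with the dye term, 49 with 24 h terms and 40 with the run block, and ranged from 9 to 118. Of the 31 entrained probes 27 passed with all arrays and 30 with the dye term. Of the 79 mock probes 40 passed with median centring, 22 in the authors' value table, 64 with all arrays and 73 with the dye term. The 0 entrained rhythms became 4 without the dimmest probes, 12 with all arrays, 22 with the dye term, 1 with a quadratic trend and 1 with the run block, and ranged from 0 to 17. The 0 mock rhythms became 2 with all arrays and 2 with the dye term. The 0 rhythm differences ranged from 0 to 1 with 1 part left out, and the 0 slope differences became 2 without 1500 and 1620 min. The 1 list differing between the arms became 0 without background correction (mean -0.10 against -0.17), 0 with an estimated correlation and 0 with the run block (mean -0.20) or with both, and the 0 list calls over 2 arms and their slope difference became 1 without background correction (cobalamin synthesis, entrained slope) and 2 with the run block and 2 with an estimated correlation besides, both times those of cobalamin synthesis (entrained slope and slope difference).

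Signs turned for genes that did not pass. For the arm difference these were bat (-0.017 without background correction), thiC (-0.031 with median centring, -0.046 in the authors' value table) and arcA (-0.070 and -0.046 under the same, -0.000877 with the run block, -0.019 within the shared run, -0.000489 without 1500 and 1620 min). With 1 part left out bat ranged from -0.050 to 0.12 and arcA from -0.043 to 0.054. For entrained slopes they were hop (0.075 in the authors' value table, 0.062 with 24 h terms, 0.032 with the run block, 0.071 without 1500 and 1620 min, and -0.16 to 0.054 with 1 part left out) and sop1 (0.0046 with the run block). For mock slopes they were purM (0.0095 without background correction), sop2 (-0.013 with 24 h terms) and phoU (-0.18 to 1.18 with 1 part left out). For slope differences they were moaA (-0.061), purM (-0.12) and sop2 (-0.10) without background correction, sop2 (-0.067) and arcA (-0.020) with median centring, truA (0.00936) and sop2 (-0.14) in the authors' value table, and sop2 (-0.13) with the run block. With 1 part left out slope differences ranged from -1.54 to 0.16 for endA, -2.28 to 0.29 for truA, -1.28 to 0.043 for hisD, -0.068 to 0.18 for hop, -0.25 to 0.35 for sop2 and -0.13 to 0.30 for arcA.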

Other observations

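The tests in this part were chosen after the counts they bear on were seen, except those of 5 further lists given at the end. For array run, a lasting difference, the order of time points, the 1500 and 1620 min samples, the shared change over time and the mean slope, the bounds were written before the tests were run, and the regroupings of the other counts and the test of array order were set out afterwards. The mean of the 2 slopes per 24 h, not among the comparisons fixed beforehand, was tested against no change and called 172 of 2400 probes, 90 rising and 82 falling (limma). A trend in 1 arm alone can move this mean, so a call does not show a trend in both arms. When each arm was tested by itself, 25 probes passed in both. For the mean slope the split was 98 rising and 60 falling of 158 with median centring, and 83 rising and 24 falling of 107 in the authors' value table. Among 15 named genes, the falling ones were argH at -1.30 ± 0.09 (SE), carB at -0.41, glyA at -0.40, cobN at -0.32, the molybdenum cofactor gene moaC at -0.31, cheY at -0.29 and htr6 at -0.25. The rising ones were infB at 0.54 ± 0.11 (SE), the ribosomal protein gene rpmC at 0.40, gdhB at 0.31, rimI at 0.30, the enolase gene eno at 0.28, arcA at 0.26, htr2 at 0.22 and thiC at 0.21. All 15 kept their sign under these scalings and without background correction, but calls ended for 3 without background correction (infB at 0.26, carB at -0.19 and htr6 at -0.17) and for 4 with median centring (arcA at 0.22, htr2 at 0.20, cheY at -0.20 and htr6 at -0.24). In the authors' value table they ended for 9, with slopes of 0.21 for infB, -0.09 for carB, -0.11 for htr6, 0.27 for arcA, -0.26 for moaC, -0.18 for cheY, -0.28 for glyA, 0.36 for thiC and 0.42 for rpmC. Of 100 orders of the time points applied alike to both arms, 1, the real one, gave as many probes, against 136 in the highest of the others. Random orders treat the time points as exchangeable, which they are not where values drift. They therefore cannot exclude chance for this count, and orders with so many calls point to structure among the samples.

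The slopes of the arms correlated across probes (r = 0.489, across genes, which are not independent replicates), above the highest of 99 random orders of the mock time points (0.442). That is consistent with a change over time common to both arms. Array order cannot be told apart from it, because array number rose with time in both arms (rank correlation 1). A biological source such as culture age stays untested.

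Probes that differed between the arms over the whole window form the pattern a reader would most want to follow up. Swapping the arms within time points gave as many as 42 probes in 1 of 100 splits, the real one. The highest of the others gave 4, so the difference recurred over the times. Swaps break up any lasting offset between the 2 arms, whatever its source, so they cannot exclude a chance difference between cultures. The real split also largely follows the array runs. The 100 probes with the smallest p at the 9 times whose arms lay in different runs kept their sign for 79% of probes at 2520 and 2700 min, where both arms lay in the same run (95% exact binomial interval 69.7% to 86.5%, too narrow because probes share samples). Their median difference was 0.15 there against 0.25 at the 9 times, a ratio of 0.594. The bound of 75% written beforehand was exceeded by less than this spread, an interval added once the value was seen. It was exceeded on 2 times only, so array run and a lasting difference between the arms cannot be told apart for these probes. A step between the 2 array runs of the entrained arm, beside a linear trend, passed for 0 of 2400 probes (limma). For 206 probes it had an unadjusted p under 0.05, where chance gives 120. No bound was set for this step, and it does not decide the question because run and time ran together in that arm.

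The entrained arm had more probes with an unadjusted 24 h rhythm than the mock arm, 361 against 111, but a period of 18 h gave 593 against 104, so the excess was not particular to 24 h, and the entrained number was 187 without 1980 min and 587 without 2880 min. The samples at 1500 and 1620 min, which scored highest among entrained samples on the first sample component (0.60 and 0.26), are not the whole cause, since without them the ratio of the counts was 2.49, from 406 against 163. A constant step between array runs is not the whole cause either, since with the run as a block the ratio was 3.98, from 255 against 64. Both counts fell with the block. Run and time ran together in the entrained arm, so the part that array run had in the excess cannot be told. Chance in the order of the time points stays open, since 10 of 100 orders gave as many entrained probes, the highest 533. A rhythm left by entrainment also stays open as untested by these counts, with 0 probes passing for the difference between the arms.

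For counts past the threshold, 10 of 100 orders of the time points gave at least the 31 entrained trends, with up to 288, so chance cannot be excluded there and such orders point to structure among the entrained samples. For the 79 mock trends only 1 of 100 orders, the real one, did, against 8 in the highest of the others. With 0 probes passing, all 100 regroupings gave as many for rhythm in the entrained arm (highest of the others 112), rhythm in the mock arm (1), the rhythm difference (0) and the slope difference (1).

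A further 5 lists were chosen from the annotation before any gene was tested. None passed for the arm difference, with adjusted p of 0.206 for histidine synthesis (mean 0.09), 0.263 for thiamine, 0.579 for histidine degradation, and 0.785 for glycolysis and gluconeogenesis and for protein translocation (camera). None passed for a slope, with a smallest adjusted p of 0.465 in the entrained arm, 0.841 in the mock arm and 0.879 for the difference. The first sample component held 23% of the variance and the entrained 1500 min sample lay farthest out on it at 0.60, against at most 0.27 for the mock samples.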
